A study of Rattus norvegicus with 6 samples.

How the data were processed

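Total RNA from primary cultures of rat testis cells, labelled as Sertoli cells, was measured on 6 Affymetrix arrays, 3 from 9-day-old and 3 from 21-day-old rats. Per the labels' protocols, decapsulated testes were digested into a cell suspension, the cells were plated in medium with 10% fetal bovine serum, and the medium was renewed after 24 hours to purify the Sertoli cells further. RNA was extracted with Trizol and labelled with biotin through a whole-transcript kit. The type recorded for the series names binding by array, whereas the labels describe total RNA and gene expression, and the values were treated as expression. Samples were assigned to an age by their titles, which also give the replicate numbers 1 to 3. The labels do not say whether replicates came from separate rats or cultures, so p-values measure only the spread between these samples, which may be technical.

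The deposited values are log2 values, made by the authors with RMA, per the submitters' processing notes. RMA corrects the background, normalizes probes between arrays by quantiles and summarises them per probe set. Its version and settings are not given in the sources used here. The table held 29214 probe sets for 6 arrays. Background signals, detection calls, scan dates and slides were not used here, so the limit of detection is unknown and batches could not be tested. RMA sets no zero, and levels of different probe sets were not read as amounts of transcript. Mean signal served to choose a probe set per gene, to filter, and to match lists of like signal. A few signals were also placed within the range of the arrays, as a rough guide to low or high signal.

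Genes were named through the platform annotation of the probe sets. It names genes for 15633 probe sets, 15310 of them with 1 gene and 323 with several. The other 13581 are unnamed here and entered only one alternative. The Entrez numbers of 15279 of the probe sets with 1 gene were found in the RefSeq gene table of assembly GRCr8, and this changed 0 symbols. No coordinates are given, since the build of the array is not stated. For 527 genes with more than 1 probe set, the one with the highest mean over all arrays was used, which left 14506 genes.

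The ages were compared in limma 3.58.1 with R 4.3.3 by lmFit and eBayes, as 21 days minus 9 days, without covariates or a filter on level. P-values were adjusted by the Benjamini-Hochberg method over all genes, with a threshold of 0.05, and a second count required a fold of at least 2. For 27 lists of genes, written from general knowledge of Sertoli cells, the cell cycle, cell death and other testis cells, camera tested two-sided whether a list shifted against all other genes, with its preset correlation of 0.01 and adjustment over the 27 lists. Of 728 list entries 95 were not named on the array. Camera with an estimated correlation and fry, which asks whether the genes of a list move on balance in 1 direction or change in either, were alternatives. Fry does not compare a list with other genes. Members were also counted with p-values adjusted over the list alone. List means per array are means of the log2 values of the members, compared by exact permutation where a p is given. This permutation ignores the replicate numbers. None of the 7 lists called by camera kept its call with an estimated correlation. Median, mean and test differed in sign only among lists that were not called: apoptosis inhibitors, hormone receptors, extracellular matrix, macrophages, spermatids and reference genes. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

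The lists, tests and alternatives were fixed before the data were examined, and so was the rule for named genes. It takes the 10 largest rises and 10 largest falls among genes that pass the threshold without overlap between the ages, up to 3 passing members of each list or, where none passes, the 2 with the largest difference, and a set of markers of Sertoli cell maturation and division. Since no gene passed, the 10 largest rises and 10 largest falls without overlap were named as an addition made after the data were seen, as were 3 alternatives: leaving out both arrays numbered 3, and the replicate block together with either a robust trended prior or only the 7253 genes of highest mean kept. Members of lists that passed only when adjusted over the list alone or with the block, and Gpx3 and Gsta4, were also named after their values had been seen. The alternatives fixed beforehand were the replicate block, keeping the 10879 or 7253 genes of highest mean, other scalings, the mean over probe sets, other variance models, array weights and leaving out each array.

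Arrays of the same number deviated together from the means of their ages. Across genes, these deviations correlated at 0.439, 0.549 and 0.673 for the numbers 1, 2 and 3, each above the 0.1 set as the limit, so the numbers were taken to pair the arrays. The pairing comes from the titles, which do not say what a number stands for. In the fit with the replicate number as a block, the number itself passed an adjusted p under 0.05 for 13 genes and an unadjusted p under 0.05 for 3238, or 22.3% of those tested.

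The gene test was tested on 20 simulated data sets of 14506 genes with the means, number effects and noise of the real arrays and 200 changed genes. Without the block it recovered 60.7% of genes changed by 1 on the log2 scale and 90.9% of those changed by 2, with 1.35 false calls on average, and with the block 67.5% and 91.9%, with 4.6 false calls. Camera detected a simulated shift of -0.4 of the mitosis list in 20 of 20 data sets and called 0 lists when nothing was shifted. The simulated noise is independent between genes, so this does not test the preset correlation. Each gene's noise was its own residual SD in the real fit with the block, an uncertain estimate from few arrays. The shares recovered hold for that noise only and do not give the power in the real data. There, 62 genes differed by at least 2-fold and 0 passed.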

Results

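The series measured gene expression in cultures of testis cells, labelled as Sertoli cells, from rats of 2 ages. Sertoli cells are the somatic cells of the seminiferous tubule that nurse the germ cells. They divide in the young testis and then stop dividing as they take up their adult functions. Cells from testes of 9-day-old and 21-day-old rats were grown in medium with 10% fetal bovine serum, and the labels place the younger cells in the phase of proliferation. Each age had 3 arrays, 6 in all, and the values were on the log2 scale. The medians of the arrays lay between 3.78 and 3.87. After restriction to probe sets with 1 gene symbol, 14506 genes were compared. The number of arrays limits the precision, with a median SE of 0.112 for a difference between the ages on the log2 scale. The study asked which genes of proliferation, the cell cycle and cell death differ between the ages.

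The arrays resembled each other closely, and both replicate number and age set them apart. Pearson correlations across the genes, which are not independent replicates, ran from 0.978 to 0.995 between arrays of 1 age and from 0.990 to 0.995 between arrays of the same number at the other age. The arrays numbered 3 stood apart at both ages. The first principal component held 50.8% of the variance and placed them at 18.8 (9 days) and 32.5 (21 days), while the other 4 arrays lay between -21.2 and -8.91. The second, with 21.3%, parted the ages, with 11.3, 4.20 and 16.4 at 9 days and -0.39, -16.0 and -15.4 at 21 days. The array nearest to 9-day-old replicate 1 and to each 21-day-old replicate was the one of the same number at the other age. For 9-day-old replicates 2 and 3 it was 9-day-old replicate 1 instead. The mean correlation was 0.993 between arrays of the same number and 0.988 between arrays of the same age. In the arrays numbered 3 the markers of smooth muscle cells were on average 1.07 (9 days) and 1.29 (21 days) higher on the log2 scale than in the other arrays of their age. Genes of oxidative phosphorylation differed by -0.32 and -0.47 in the same arrays.

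**Figure D1:**
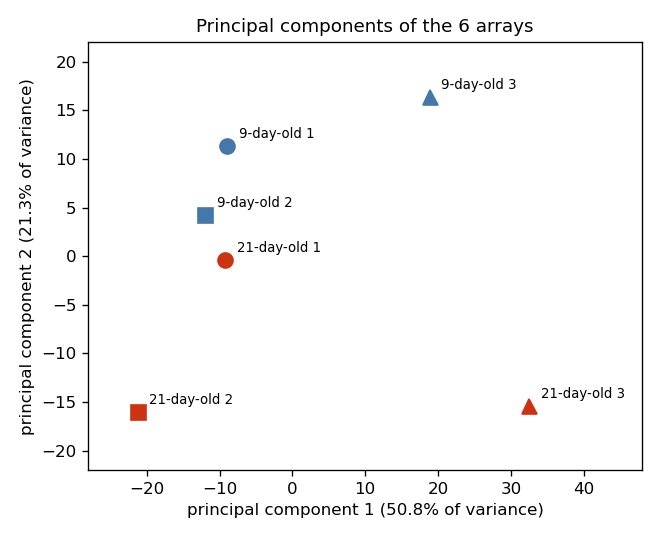
Scores of the 6 arrays on the first principal component (x axis, 50.8% of the variance) and the second (y axis, 21.3%), computed from the log2 values of 14506 genes; each point is 1 array, blue for 9 days and red for 21 days, with its replicate number. Both arrays numbered 3 lie at the right, at 18.8 and 32.5.

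The largest differences between the ages were in transcripts higher at 21 days. Stmn2, a regulator of microtubules best known from neurons, was at 4.26 ± 0.67 at 9 days and 8.06 ± 0.30 at 21 days (log2, SD, n = 3 each), a 13.9-fold difference. Tf, the iron carrier transferrin and a classic secreted product of Sertoli cells, was at 5.82 ± 0.63 and 9.41 ± 1.51 (SD, n = 3 each), a 12.1-fold difference. The log2 differences were 2.34 ± 0.69 (SE) for the adhesion gene Mpzl2, 2.28 ± 0.77 for Testin, which encodes a protein secreted by Sertoli cells, 2.19 ± 0.45 for the reductase gene Akr7a3 and 2.19 ± 0.71 for Tmem184a. They were 2.15 ± 0.54 for the gelatinase gene Mmp9, 2.03 ± 0.42 for Hpx, which encodes the heme carrier hemopexin, 2.02 ± 0.46 for Il1rn, the antagonist of the interleukin receptor, and 1.82 ± 0.28 for the membrane peptidase gene Mme. Several of these differences were largest in 21-day-old replicate 3: without that array the difference was 2.73 for Tf, 1.52 for Mpzl2, 1.35 for Testin and 1.34 for Tmem184a.

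Transcripts lower at 21 days differed less in size. The receptor phosphatase gene Ptprz1 was at 5.18 ± 0.31 at 9 days and 3.91 ± 0.24 at 21 days (log2, SD, n = 3 each), or 0.417 of the younger level. The log2 differences were -1.20 ± 0.41 (SE) for the surface glycoprotein gene Cd24, -1.16 ± 0.37 for Cimap1c, -1.04 ± 0.43 for the membrane metalloproteinase gene Mmp16, -0.98 ± 0.28 for the glypican gene Gpc3 and -0.94 ± 0.27 for the transglutaminase gene Tgm1. They were -0.88 ± 0.33 for the growth factor gene Mdk, -0.86 ± 0.27 for the protocadherin gene Dchs1, -0.85 ± 0.12 for Igf2bp1, which encodes an RNA-binding protein of fetal tissues, and -0.82 ± 0.23 for the imprinted zinc finger gene Plagl1. Without a single array Mmp16 differed by -0.61 (21-day-old replicate 3), Cimap1c by -0.76 (9-day-old replicate 3) and Mdk by -0.56 (9-day-old replicate 2). Of all 82 genes named by rule, 52 had a difference over 1.5 times smaller, or turned, without 1 of the arrays, and 28 over 2 times smaller or turned. The values without that array are given beside the genes below or at the end. The 20 genes with the largest rises and falls given so far had no overlap between the 3 values of one age and the 3 of the other. They are the 10 largest of each kind without overlap, named after the values had been seen, since no gene passed the test.

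None of the 14506 genes passed an adjusted p under 0.05 in limma, so none passed it with a fold of at least 2. The lowest adjusted p was 0.685. At an unadjusted p under 0.05 there were 431 genes, 211 higher and 220 lower at 21 days, against 725.3 by chance. That 725.3 holds for arrays without shared replicate numbers. Without the block, pairing by number adds to the spread and can make low p-values rarer, so the deficit does not mean less difference than chance. With the replicate number as a block there were again 0 genes, with 1122 at an unadjusted p under 0.05, above the 725.3, and a lowest adjusted p of 0.132. Differences of at least 2-fold at any p were seen for 62 genes, 51 higher and 11 lower at 21 days. The values of the ages did not overlap for 830 genes, 5.72% of those tested, against 10% by chance. That 10% holds for arrays without shared replicate numbers, and pairing by number can make overlap more frequent.

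Genes of cell division were lower in the cultures from older rats. The list of mitosis and spindle genes fell from a mean log2 value of 7.15 ± 0.24 at 9 days to 6.76 ± 0.30 at 21 days (SD, n = 3 each), or 0.760 of the younger level. All 38 measured members were lower at 21 days, and the mean of the list was lower in each of the 3 pairs of arrays with the same number, by -0.29, -0.40 and -0.50. The means of the ages overlapped, with an exact two-sided permutation p of 0.20, where 0.10 is the smallest possible. Bub1b, a kinase of the spindle checkpoint, differed by -0.62 ± 0.27 (log2, SE), and Nusap1, which binds spindle microtubules, by -0.57 ± 0.30, or by -0.34 without 9-day-old replicate 1. Camera, limma's test of a list against all other genes, gave the fall of the list an adjusted p of 7.27e-19 with its preset correlation between genes. The adjusted p was 0.502 with an estimated correlation. Over all genes 0 of the members passed. Adjusted over the list alone, 2 passed, Aurkb (-0.47 ± 0.07) and Kif18b (-0.53 ± 0.09), which encode a mitotic kinase and a mitotic motor and are named because they were so few. With the replicate number as a block, 34 of the 38 passed when adjusted over the list alone, all of them lower.

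DNA replication genes fell as a list too, from 6.65 ± 0.13 at 9 days to 6.42 ± 0.13 at 21 days (mean log2, SD, n = 3 each). All 36 measured members were lower at 21 days, and the exact permutation p of the list means was 0.10. The polymerase gene Pole differed by -0.48 ± 0.25 (log2, SE), or by -0.24 without 9-day-old replicate 3, and the thymidylate synthase gene Tyms by -0.43 ± 0.17. The adjusted p from camera was 4.42e-12, and 0.502 with an estimated correlation. No member passed over all genes or adjusted over the list alone. The G1 cyclins, their kinases and the E2F factors fell with a median log2 difference of -0.15, and 14 of 19 members were lower, with an exact permutation p of 0.20 for the list means. Ccnd2, a D-type cyclin of G1, was at 9.03 ± 0.16 and 8.53 ± 0.36 (SD, n = 3 each), a difference of -0.50 that was -0.30 without 21-day-old replicate 1, and E2f5 differed by -0.46 ± 0.15 (SE). The adjusted p of this list was 0.00831, and 0.502 with an estimated correlation. It was 0.232 without 9-day-old replicate 2. No member passed over all genes or adjusted over the list alone.

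Inhibitors of the cell cycle were not shifted as a list, with 10 of 21 members higher at 21 days, a median log2 difference of -0.012 and an adjusted p of 0.915 from camera. Cdkn1b, which encodes p27, differed by -0.22 ± 0.15 (log2, SE) and Cdkn1a, which encodes p21, by -0.13 ± 0.40, and the sign for Cdkn1a turned when 21-day-old replicate 3 was left out (0.24). The largest differences in this list were -0.40 ± 0.18 for Cdkn2c and -0.35 ± 0.22 for Wee1, a kinase that holds back entry into mitosis (-0.11 without 21-day-old replicate 2). No member passed over all genes or adjusted over the list alone. The proliferation marker Mki67 was not analysed here, since the probe table used names no probe set for it.

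Genes of cell death showed no shift between the ages. Of 33 measured promoters of apoptosis 19 were higher and 14 lower at 21 days, with a median log2 difference of 0.045 and an adjusted p of 0.571 from camera. The largest differences were 0.30 ± 0.33 (SE) for Bid, a trigger of the mitochondrial pathway, and 0.29 ± 0.44 for the kinase gene Dapk1. Without 9-day-old replicate 3 Bid differed by 0.077 and the sign for Dapk1 turned (-0.00022). Of 17 inhibitors of apoptosis 6 were higher and 11 lower, with a median of -0.058 and an adjusted p of 0.953. Bcl2, which blocks the mitochondrial pathway, was at 4.36 ± 0.59 and 5.06 ± 1.14 (log2, SD, n = 3 each), with 6.38 in 21-day-old replicate 3 against 4.37 and 4.44 in the other arrays of that age, and differed by 0.047 without it. The survival kinase gene Akt2 differed by 0.28 ± 0.11 (SE). No member of either list passed over all genes or adjusted over the list alone.

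**Figure D2:**
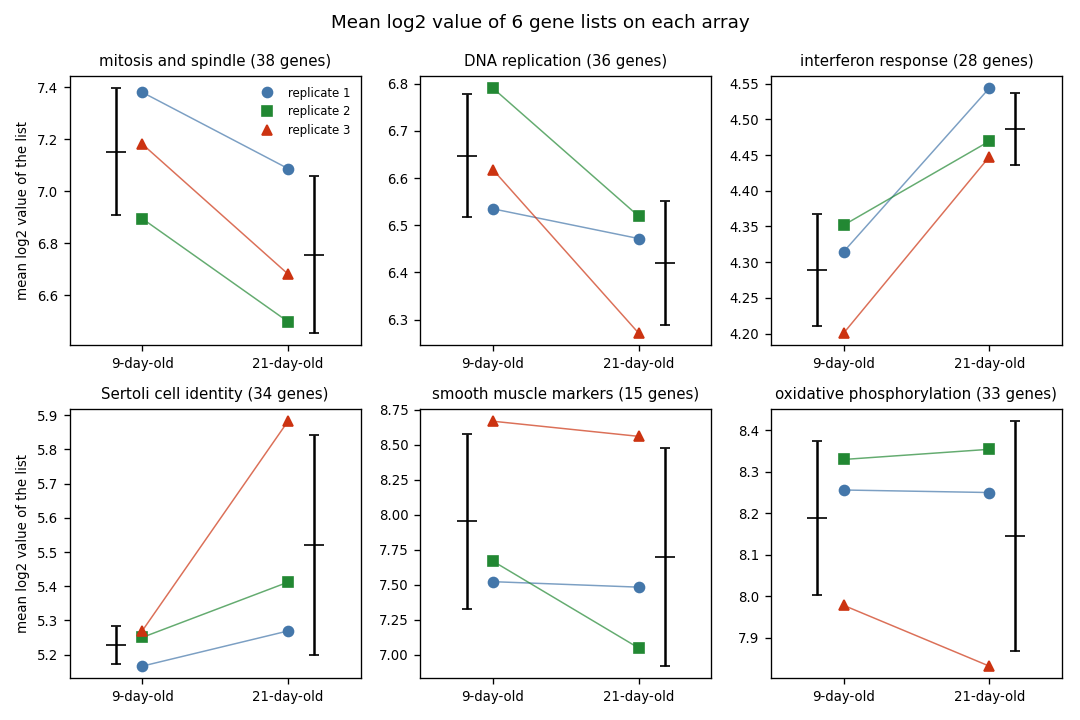
Mean log2 value (y axis) of the members of 6 gene lists on each array at 9 and 21 days (x axis); points are arrays, lines join arrays of the same replicate number, and the black marks give the mean and SD of 3 arrays. The mitosis list is lower at 21 days in each pair (-0.29, -0.40 and -0.50), the Sertoli list is highest in 21-day-old replicate 3, and the smooth muscle and oxidative phosphorylation lists set the arrays numbered 3 apart at both ages.

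Genes that mark Sertoli cell identity rose as a list, from a mean log2 value of 5.23 ± 0.06 at 9 days to 5.52 ± 0.32 at 21 days (SD, n = 3 each), and 26 of 34 members were higher at 21 days, with an exact permutation p of 0.20 for the list means. Tf and Shbg, which encodes the androgen-binding protein secreted by Sertoli cells, had the largest differences, 3.59 ± 0.78 and 1.16 ± 0.61 (log2, SE). Shbg differed by 0.46 without 21-day-old replicate 3. The camera adjusted p was 9.56e-05 and the median log2 difference 0.12. With an estimated correlation the adjusted p was 0.542. The shift of the list was 0.10 and 0.16 in the first 2 pairs of arrays and 0.61 in the pair numbered 3, the arrays that stand apart. Without 21-day-old replicate 3 the adjusted p was 0.493 and the median 0.062. Without both arrays numbered 3, an alternative chosen after the data were seen, these were 0.196 and 0.049. Adjusted over the list alone, no member passed, and 1 member, Tf, passed with the replicate number as a block.

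Other markers of Sertoli cell maturation named beforehand differed little. Amh, the hormone that immature Sertoli cells secrete, was at 3.14 ± 0.09 and 3.35 ± 0.12 (log2, SD, n = 3 each). The receptor for follicle-stimulating hormone, Fshr, was at 2.57 ± 0.13 and 2.89 ± 0.51, and the tight junction gene Cldn11 at 3.05 ± 0.21 and 3.42 ± 0.25. Log2 differences were 0.22 ± 0.13 (SE) for the transcription factor gene Wt1, 0.18 ± 0.09 for Gata1, -0.018 ± 0.18 for the inhibin subunit gene Inhbb and -0.14 ± 0.11 for the thyroid hormone receptor gene Thra. Without 21-day-old replicate 3 the differences were 0.025 for Fshr, 0.10 for Wt1 and -0.063 for Thra, and without 21-day-old replicate 1 the sign for Inhbb turned (0.18). None of these passed over all genes. The means of Amh, Fshr, Gata1 and Cldn11 at both ages lay below the medians of all arrays, 3.78 to 3.87. Fshr in the younger cultures, at 2.57, also lay below the lower quartiles of all arrays, 2.61 to 2.65. No detection calls were used here, so whether these signals exceeded background is unknown. For Amh, Fshr, Gata1 and Cldn11 a small difference therefore does not show that expression stayed the same with age. Sox9 was not analysed here, since no probe set is named for it.

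**Figure D3:**
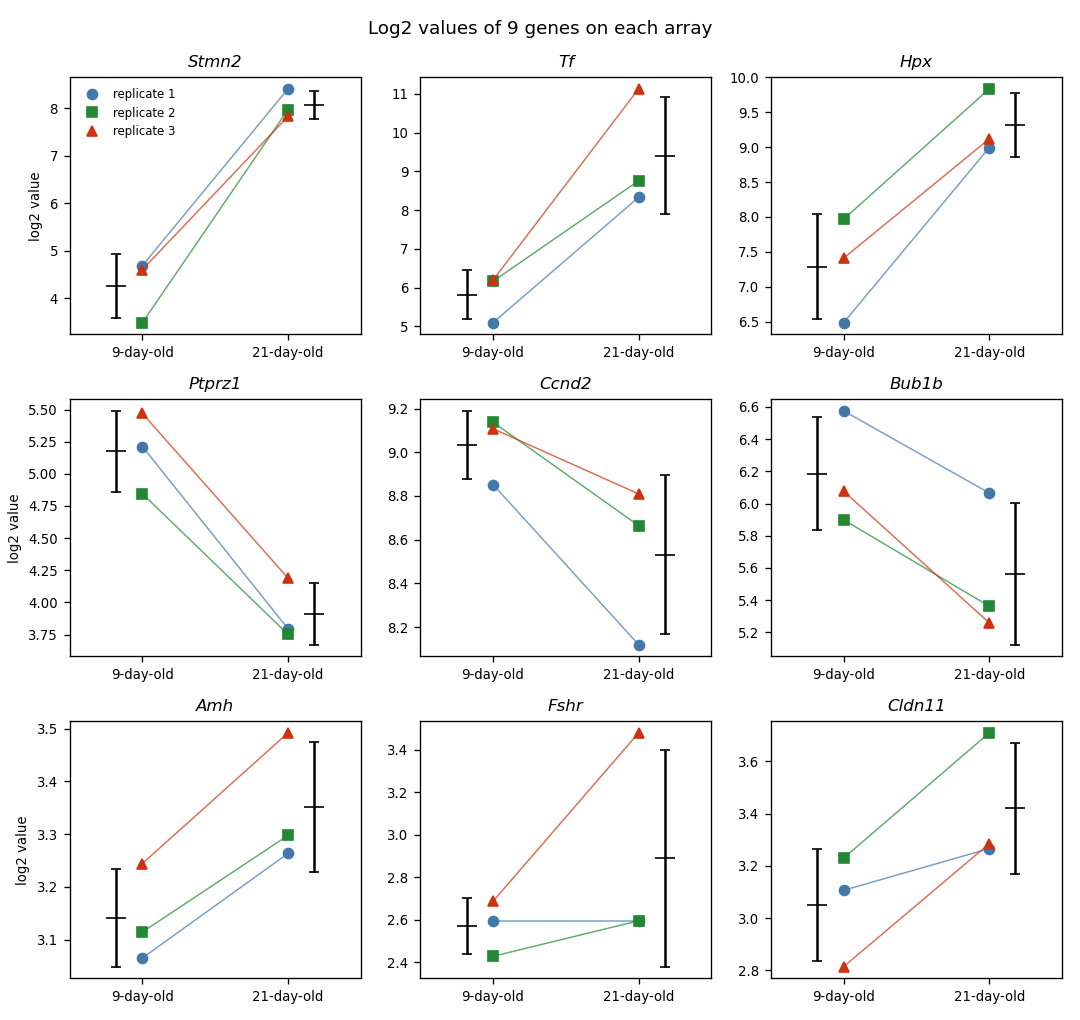
Log2 values (y axis) of 9 genes on each array at 9 and 21 days (x axis); points are arrays, lines join arrays of the same replicate number, and the black marks give the mean and SD of 3 arrays. The y axes differ between genes: Stmn2 spans 3.49 to 8.40, while Amh stays between 3.07 and 3.49.

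With all 6 arrays, all genes kept and no rescaling, none of the 5 lists of Sertoli cell functions was shifted, with adjusted p from camera between 0.178 and 0.915. Tight and adherens junction genes had 15 members higher and 15 lower, with an adjusted p of 0.374, although F11r, a junctional adhesion molecule, differed by 1.61 ± 0.32 (log2, SE) and the tight junction gene Ocln by 0.97 ± 0.56, or by 0.30 without 21-day-old replicate 3. With the replicate number as a block, F11r and Espn, an actin bundler of the Sertoli cell junction that is named because of this pass (0.76 ± 0.23), passed when adjusted over the list alone. The junction list was called higher without 21-day-old replicate 2 (median 0.098, adjusted p 0.00996). Glycolysis and lactate supply genes had 18 of 24 members lower and an adjusted p of 0.915. They were called lower without 21-day-old replicate 2 (median -0.15, adjusted p 0.0248) and higher without 21-day-old replicate 3 (0.037, adjusted p 0.0377). In this list the glucose transporter gene Slc2a3 differed by 0.56 ± 0.11 and the lactate carrier gene Slc16a7 by -0.86 ± 0.48, or by -0.45 without 21-day-old replicate 2. Slc2a3 passed over the list alone with the block, as did Pde4d among the hormone receptor and signalling genes.

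Pde4d, a phosphodiesterase that degrades cyclic AMP, differed by 0.48 ± 0.09 (log2, SE) and the insulin receptor gene Insr by -0.34 ± 0.14, while their list of 28 members had an adjusted p of 0.915. Retinoid handling genes had 12 of 19 members higher and an adjusted p of 0.388, with 0.59 ± 0.22 for the retinal dehydrogenase gene Aldh1a1 and -0.77 ± 0.27 for the retinal reductase gene Dhrs3. Phagocytosis and lysosome genes had 20 of 31 members higher and an adjusted p of 0.178, and were called higher with only the 7253 genes of highest mean kept (0.0174) and after quantile normalization (0.0374). Elmo1, which acts in engulfment, differed by 1.64 ± 0.68, with 6.36 in 21-day-old replicate 3 against 3.69 and 4.24 in the other arrays of that age, and Psap, a lysosomal protein precursor, by 0.33 ± 0.15. No member of these 5 lists passed over all genes or, without the block, adjusted over the list alone.

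Interferon response genes rose as a list, from a mean log2 value of 4.29 ± 0.08 at 9 days to 4.49 ± 0.05 at 21 days (SD, n = 3 each), and 25 of 28 members were higher. Psmb8, a subunit of the immunoproteasome, differed by 0.49 ± 0.29 (log2, SE) and the antiviral membrane protein gene Bst2 by 0.48 ± 0.20. Psmb8 differed by 0.22 without 9-day-old replicate 3. The means of the list did not overlap between the ages, and an exact two-sided permutation test, which ignores the replicate numbers, gave p = 0.10, the smallest that 3 against 3 allows. In the pairs of arrays with the same number the list differed by 0.23, 0.12 and 0.25. The adjusted p from camera was 9.79e-08, and 0.115 with an estimated correlation. No member passed over all genes or adjusted over the list alone, and 1, Psmb8, passed over the list alone with the replicate number as a block.

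Metabolic, matrix and stress lists were not shifted. Adjusted p from camera was 0.527 for oxidative phosphorylation, with 25 of 33 members lower and -0.21 ± 0.15 (log2, SE) for Ndufs4 and -0.20 ± 0.14 for Uqcrb, both parts of the respiratory chain (-0.064 and -0.087 without 21-day-old replicate 3). This list moved with the arrays numbered 3 (-0.32 and -0.47), and its call changed with single arrays. It fell with a median of -0.13 and an adjusted p of 0.000434 without 9-day-old replicate 3, it fell without 21-day-old replicate 2 (-0.15, adjusted p 0.00251), and it rose without 21-day-old replicate 3 (0.13, adjusted p 0.00402). Cholesterol synthesis genes had an adjusted p of 0.954, with 0.23 ± 0.14 for Hsd17b7 and 0.13 ± 0.21 for the sterol regulator gene Insig1, whose sign turned without 9-day-old replicate 1 (-0.053). They rose without 9-day-old replicate 3 (median 0.11, adjusted p 0.00890).

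Extracellular matrix genes had 13 members higher and 13 lower and an adjusted p of 0.915. The collagen gene Col12a1 differed by -0.67 ± 0.54 and the matrix gene Tgfbi by 0.79 ± 0.39 (log2, SE), and Col12a1 and the laminin gene Lama1, which is named because of this pass (-0.48 ± 0.29), passed over the list alone with the block. Without 9-day-old replicate 3 Col12a1 differed by -0.21 and the list rose (median 0.074, adjusted p 0.0153). Immediate early genes of the serum and stress response had an adjusted p of 0.192, with 0.29 ± 0.12 for Ier3 and 0.27 ± 0.29 for the nuclear receptor gene Nr4a1 (0.011 without 21-day-old replicate 2). Reference genes had a median difference of -0.011 and an adjusted p of 0.954. The largest differences among them were 0.38 ± 0.10 for B2m, the light chain of class I histocompatibility molecules, and -0.42 ± 0.30 for the transferrin receptor gene Tfrc (-0.12 without 21-day-old replicate 2).

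Markers of other testis cells were examined because the cells came from digested testes. The smooth muscle actin gene Acta2 lay between 11.5 and 12.9 on the 6 arrays, whose highest values were 12.7 to 12.9. The differences between the ages are therefore those of whole cultures and were not assigned to Sertoli cells alone. Fibroblast and stroma markers fell as a list, with 14 of 19 members lower, an exact permutation p of 0.80 for the list means, a median log2 difference of -0.15 and an adjusted p of 0.0350 from camera, and of 0.502 with an estimated correlation. This call also ended under 5 other filters, scalings and weights (adjusted p 0.0522 to 0.165) and without any of 3 single arrays, 9-day-old replicate 3 (0.357) and 21-day-old replicates 1 (0.170) and 3 (0.226). Without both arrays numbered 3 its adjusted p was 0.722. Dpt and Thy1, both markers of fibroblasts, went the other way, at 2.83-fold (log2 SE 0.88) for Dpt and a log2 difference of 1.03 ± 0.40 (SE) for Thy1. Without 21-day-old replicate 2 the log2 difference of Dpt was 0.47. Adjusted over the list alone 1 member passed, the growth factor receptor gene Pdgfrb (-0.61 ± 0.12), named because it was the only one. With the replicate number as a block 4 passed, 3 lower and 1 higher.

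Markers of peritubular myoid and smooth muscle cells had 13 of 15 members lower at 21 days, a median log2 difference of -0.24 and an adjusted p of 0.300. With the replicate number as a block the adjusted p was 0.00445 and the list was called lower, and 0.757 with both the block and an estimated correlation. Without 21-day-old replicate 3 its median was -0.55 and its adjusted p 8.26e-05, and without 9-day-old replicate 1 these were -0.37 and 0.0494. The direction turned without 9-day-old replicate 3 (median 0.066), and the median was also above 0 without 21-day-old replicate 2, neither past the threshold. The smooth muscle actin gene Actg2 differed by -0.70 ± 1.02 (SE) and the myosin kinase gene Mylk by -0.69 ± 0.37, and without 9-day-old replicate 3 Mylk differed by -0.31 and the sign for Actg2 turned (0.038). No member passed over all genes or adjusted over the list alone. Leydig cell markers had an adjusted p of 0.178, with 8 of 13 members higher, 5 lower and a median log2 difference of 0.021. Their list mean was 4.36 ± 0.05 at 9 days and 4.57 ± 0.06 at 21 days (log2, SD, n = 3 each). It did not overlap between the ages (exact permutation p 0.10) and was higher in each pair, by 0.20, 0.23 and 0.20. The largest differences were 1.59 ± 0.43 (SE) for the steroid reductase gene Akr1c14 and 0.98 ± 0.38 for Hsd11b1, which interconverts glucocorticoids. Both passed over the list alone with the block. The list mean differed by 0.21, far above the median of 0.021, so its rise rests mainly on Akr1c14 and Hsd11b1.

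Spermatocyte markers rose as a list by a median of 0.062, from a mean of 2.81 ± 0.04 to 2.89 ± 0.16 (log2, SD, n = 3 each), with 23 of 29 members higher, an exact permutation p of 0.60 for the list means and an adjusted p of 0.0339 from camera. The adjusted p was 0.782 with an estimated correlation and 0.0560 with the replicate block. Without 21-day-old replicate 3, one of the arrays that stand apart, it was 0.884 with a median of -0.0038, and without both arrays numbered 3 it was 0.783. The call also ended without 9-day-old replicate 2 (0.175) and without 21-day-old replicate 2 (0.0583). The meiotic gene Hormad1 differed by 0.58 ± 0.24 (SE) and Mybl1, a factor of meiotic transcription, by -0.41 ± 0.36, or by -0.054 without 21-day-old replicate 2. Adjusted p was 0.657 for spermatogonia, with 0.25 ± 0.13 for Id4 and -0.22 ± 0.08 for Zbtb16, and 0.915 for spermatids, with 0.19 ± 0.07 for Catsper3 and -0.15 ± 0.11 for Izumo1 (-0.057 without 9-day-old replicate 2). Many of these signals were low: 10 of 29 spermatocyte markers and 10 of 20 spermatid markers were among the 10879 genes of highest mean. Whether the dimmer markers exceeded background is unknown, so their differences may not reflect transcripts.

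Markers of blood and vessel cells were not shifted when all genes were kept. Macrophage markers had a median log2 difference of -0.028 and an adjusted p of 0.987, against 0.73 and 0.0449, called higher, with only the 7253 genes of highest mean kept, where 2 of the 22 members, Lcp1 and Cd14, were left. The largest differences were 1.22 ± 0.82 (log2, SE) for Lcp1 and 0.24 ± 0.21 for Cd14. Lcp1 differed by 0.29 without 21-day-old replicate 3, and Cd14 by 0.043 without 9-day-old replicate 3. Endothelial markers had an adjusted p of 0.826, with 0.73 ± 0.48 and -0.94 ± 0.55 for the growth factor receptor genes Flt4 and Flt1. Flt4 differed by 0.19 without 21-day-old replicate 3. Erythroid markers had an adjusted p of 0.571, with 0.13 ± 0.14 for the globin gene Hbb and -0.12 ± 0.09 for Hbb-b1. The sign for Hbb turned without 9-day-old replicate 1 (-0.015), and Hbb-b1 differed by -0.034 without 21-day-old replicate 1. Only 3 of 8 erythroid and 10 of 22 macrophage markers were among the 10879 genes of highest mean. For the dimmer ones, too, signal above background is unknown. No member of these lists or of the germ cell lists passed over all genes or adjusted over the list alone.

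Other named genes had differences over 1.5 times smaller without 1 array. Without 21-day-old replicate 3 the differences were 0.18 for Akt2, 0.39 for Aldh1a1, 0.14 for Amh, -0.13 for Cdkn1b, 0.85 for Elmo1, 0.34 for Hormad1 and 0.17 for Psap. Without 21-day-old replicate 1 they were -0.62 for Flt1, 0.13 for Hsd17b7 and 0.64 for Thy1, and without 21-day-old replicate 2 0.23 for Cldn11. Without 9-day-old replicate 3 they were 0.65 for Hsd11b1 and -0.20 for Insr, and without 9-day-old replicate 2 0.11 for Gata1.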

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

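The count of 0 genes, with or without a 2-fold limit, held under every alternative fixed beforehand, the replicate block among them (0, lowest adjusted p 0.132), with 189 to 1122 genes at an unadjusted p under 0.05 where genes with a symbol were tested by limma's moderated test, 309 with each gene's own variance, and 780 over all probe sets with or without a symbol. It also held without both arrays numbered 3 (0, with 505 at an unadjusted p under 0.05), an alternative chosen after seeing the data like the next 2. The replicate block with a robust trended prior called 6 genes, all at least 2-fold: Stmn2, Hpx, F11r, Gpx3 and Gsta4 higher and Ptprz1 lower, with adjusted p of 0.0377 to 0.0495. The block with the 7253 genes of highest mean called 5, of which 4 at least 2-fold: Stmn2, Hpx, Gpx3 and Gsta4, and Hsd11b1 (0.98). Adjusted p ran from 0.0173 to 1 over all alternatives of this count. Gpx3 and Gsta4 are named because they were called there.

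Of 27 lists 7 were called, and 5 to 10 under other filters, scalings, blocks and left-out arrays. With an estimated correlation 0 were called, and 0 by fry in 1 direction or mixed, which ends the calls of mitosis (-0.39), DNA replication (-0.23), G1 cyclins (-0.15), Sertoli identity (0.12), interferon response (0.20), spermatocytes (0.062) and fibroblasts (-0.15). The estimated correlation was 0.648 for mitosis, above the preset 0.01, but 0.0079 for interferon response, below it. For the interferon list a higher correlation is therefore not what ended the call by camera. Camera with an estimated correlation thus differs from camera with the preset one in more than the correlation. The calls that ended in the other lists cannot be credited to correlation between genes alone. What else ended them was not tested. Mitosis, DNA replication and interferon response passed under every other alternative, with medians of -0.56 to -0.28, -0.29 to -0.12 and 0.13 to 0.28.

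Leaving out single arrays ended or made calls of other lists, with medians of -0.23 to -0.082 for G1 cyclins, 0.062 to 0.21 for Sertoli identity, -0.0038 to 0.12 for spermatocytes, -0.27 to -0.070 for fibroblasts, -0.048 to 0.11 for junctions, -0.15 to 0.037 for glycolysis, -0.13 to 0.11 for cholesterol synthesis, -0.15 to 0.13 for oxidative phosphorylation, -0.12 to 0.074 for matrix and -0.55 to 0.066 for smooth muscle. Values labelled reversed here are calls in the other direction, and for spermatocytes a call that ended with its sign turned. They were 0.037 (glycolysis) and 0.13 (oxidative phosphorylation) without 21-day-old replicate 3, where spermatocytes were at -0.0038, and 0.11 (cholesterol synthesis) without 9-day-old replicate 3. Glycolysis was called up at 0.027 without both arrays numbered 3. The medians of smooth muscle, junctions and matrix also turned sign without a call in the other direction. The cause was not tested.

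Without both arrays numbered 3 the calls of Sertoli identity (0.049), spermatocytes (0) and fibroblasts (-0.047) ended and smooth muscle was called (-0.19). The replicate block ended the call of spermatocytes (0.062, adjusted p 0.0560), called smooth muscle (-0.24) and changed no other call; with the robust trended prior it again called smooth muscle (-0.24). The spermatocyte call also ended with 10879 genes kept by level (0.054), with quantiles (0.048), reference centring (0.078) and array weights (0.029), and the fibroblast call with 10879 (-0.15) or 7253 (-0.17) genes kept, with quantiles (-0.13), median subtraction (-0.17) and array weights (-0.16). Phagocytosis was called with 7253 genes kept (0.037) and with quantiles (0.072), and macrophages with 7253 genes kept (0.73, from 2 members). The block with 7253 genes kept called phagocytosis (0.037), macrophages (0.73, 2 members), Leydig cells (0.13, 4 members), smooth muscle (-0.28) and, reversed, endothelial cells (-0.18, 5 members), and ended fibroblasts (-0.17). Among lists not called, 101 of 416 values had another sign than in the report, and among 82 named genes 9 of 1418, for 6 genes. No rescaling moved the median of all genes by over 0.1 on the log2 scale. Signal over background was not used here, so the limit it sets for dim probe sets is unknown.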

Other observations

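Of the tests below only the one on juvenile growth genes was written down before its values were seen; the others were chosen after the results they bear on, and the gene families other than the growth genes were picked after single members had been noticed. Glutathione S-transferases, which conjugate glutathione to reactive compounds, were mostly higher at 21 days, 14 of 18 genes with a median log2 difference of 0.22 and 14 of 18 under each of 3 rescalings too. Gsta1 was at 8.94 ± 0.43 and 9.69 ± 0.31 (log2, SD, n = 3 each) and Gsta4 differed by 1.08 ± 0.80 (SE), with a spread that lies mostly between replicate numbers. The camera adjusted p over 4 such families was 8.16e-05, and 0.207 with an estimated correlation. This p includes the members that led to the choice of the family. Without Gsta1, Gsta4, Gstm6 and Mgst1, noticed beforehand, 10 of 14 were higher with a median of 0.14 and an adjusted p of 0.00306, and 0.276 with an estimated correlation. Gpx3, the secreted glutathione peroxidase, was at 7.15 ± 0.65 and 8.39 ± 0.56. Class I histocompatibility genes were higher for 20 of 25 (median 0.14, 19 of 25 with the array median subtracted), with 0.64 ± 0.10 for RT1-CE5, an adjusted p of 2.24e-05 and 0.124 with an estimated correlation. Without RT1-CE5, 19 of 24 were higher with an adjusted p of 0.000293, and 0.140 with an estimated correlation. Matrix metalloproteinases had no shift as a family (adjusted p 0.114, 15 of 21 higher), although Mmp9 was higher and Mmp16 lower.

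Igf2bp1, Plagl1, Gpc3 and Mdk, all lower at 21 days, belong to genes known to be active in growing fetal and newborn organs. This raised the hypothesis that the fall of such genes after birth, known from other organs, also holds in these cultures, and 22 further imprinted or fetal growth genes were listed before their values were seen, with the bound that at least 67 percent should be lower. Of 15 measured, 10 were lower at 21 days, 66.7%, with a median log2 difference of -0.083. The share was just under the bound, so the prediction as written was not met. The share was 60.0% with quantiles, 80.0% with the array median subtracted and 66.7% on the reference genes. Without both arrays numbered 3 it was 66.7%, with a median of -0.21. The bound was passed only with the array median subtracted, so a miss this narrow does not settle the hypothesis either way. Igf2 differed by -0.58 ± 0.18 (SE), Grb10 by -0.42 ± 0.15 and Slc38a4 by 0.38 ± 0.48. The camera adjusted p of the list was 0.0214, and 0.124 with an estimated correlation.

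The lower mitosis list at 21 days is the pattern closest to the question of the study. The list median stayed at or below -0.35 under 3 rescalings, and past the threshold with the preset correlation. These rescalings moved the median of all genes by only 0.0071, -0.019 and 0.015, on values that RMA had already normalized. They could hardly have brought the list near 0, so this check decides little about a scaling difference between the arrays. Fewer fibroblasts or smooth muscle cells at 21 days, or a slower division of those cells, may contribute: the fibroblast list had a median of -0.15, but its members spread by 0.53 (SD), too widely to decide. The smooth muscle list had a median of -0.24, with 13 of 15 members lower and a camera adjusted p of 0.300, or 0.00445 with the replicate number as a block. With both the block and an estimated correlation the adjusted p was 0.757. In the arrays numbered 3, where this list was higher by 1.07 and 1.29, the mitosis list differed by 0.044 and -0.11. These values leave the explanation open. Chance cannot be excluded with 10 splits of 6 arrays into 3 and 3, and 2 of the 10, the real one included, gave a median as far from 0, the real value being 0.39 in size and the highest other 0.56, while among the 4 splits that part all 3 pairs, again with the real one, the highest other was 0.20. Slower division of the Sertoli cells themselves with age stays open and untested.

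The rise of the Sertoli identity list is another pattern. It may rest on the culture of 21-day-old replicate 3, since without it the median was 0.062 and the call ended (adjusted p 0.493), though Tf was higher at 21 days in all 3 pairs. A larger share of Sertoli cells in the older cultures would raise all of their transcripts: 11 of 34 members were higher in all 3 pairs, against 10.7% of all genes. This is 32.4% of the members, just under the 33% set as the lower bound, so by that bound the explanation fails. The bound was set after the result was seen, and the miss is narrow. A larger share of Sertoli cells therefore cannot be told apart here from a change within the cells. Age itself stays open.

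Both arrays numbered 3 stand apart, the strongest structure in these data. The smooth muscle and oxidative phosphorylation lists moved apart by 1.39 and 1.76 in those arrays, which argues against scaling but does not exclude it. These lists were matched only roughly by signal. Their means were 7.95 and 8.19 at 9 days, with the array numbered 3 included, but 7.05 and 8.35 in 21-day-old replicate 2. More smooth muscle or peritubular myoid cells in the cultures numbered 3 may explain why those arrays stand apart. Of 15 smooth muscle markers 14 were highest in the array numbered 3 at both ages, against 18.6% of all genes and 11.1% by chance. Actg2 was at 10.5 in 9-day-old replicate 3 against 7.96 and 8.60, and Des at 10.5 in 21-day-old replicate 3 against 7.31 and 7.12. A stronger contractile program in the same cells would give the same markers, and a shared day or dish is not given in the labels, so these cannot be told apart. Oxidative phosphorylation genes were lowest there at both ages for 32 of 33 members, against 2760 of all 14506 genes.

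For the other counts, too, 10 splits are too few for a share under 0.05. All 10 splits called 0 genes, as the real one did (0, highest other 0), with or without the 2-fold limit. Camera called 7 lists in the real split and up to 9 in the others, with 5 of the 10 splits, the real one included, calling at least 7. Among the splits that part all 3 pairs the highest other was 8. The other 6 splits part only 1 pair.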
